A study of Mus musculus with 4 samples.

How the data were processed

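CTCF, a zinc finger protein that binds DNA and marks many loop anchors and domain borders together with cohesin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryos at embryonic day 13.5. The series has 4 samples: a CTCF library and an input library from the telencephalon, and a CTCF library and an input library from the medial ganglionic eminence (MGE), a ventral part of the telencephalon that gives rise to many cortical interneurons. Peak lists of the 2 CTCF libraries were used. The input libraries are not analysed here. The labels give the same age for both tissues, but the track name of the telencephalon list begins with e14, so a difference in stage is not excluded. The labels describe MGE dissection for every sample and do not say whether the telencephalon sample contained the MGE.

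Per the labels' protocols, chromatin was sonicated to about 500 bp, 1 part in 25 was kept as input, and the rest was incubated with a rabbit antibody against CTCF. The labels name different library kits for the tissues, both from New England Biolabs: its ChIP-Seq kit for telencephalon and its NEBNext Ultra II kit for MGE. Tissue and kit therefore cannot be told apart in any comparison between the lists. Per the submitters' processing notes, the tools were Bowtie2 2.3.2 and MACS2 2.1.1.20160309 and the genome build was mm10. The calling threshold, the control used in calling and any filter on peaks are not given in the sources used here. Track names in the file headers differ between the lists (p001 for telencephalon and p01 for MGE). Whether these refer to thresholds is not stated, so the MGE list may have been called with a looser one. The authors' deposited lists hold a chromosome, a start and an end per peak, with no score, summit, fold or p-value. Peak width was therefore the only property of a peak that could be used to rank it.

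With 1 CTCF library per tissue there are no replicates. No p-value was computed for any difference between tissues, and every comparison describes these 2 libraries. Shares are given with 95% exact Clopper-Pearson intervals, which cover counting error alone. For gene lists they treat genes as independent. Neighbouring genes can have the same peak, so intervals of lists such as Hox genes, protocadherins and olfactory receptors are too narrow. Peak lists hold no read counts, so the sequencing depth of the libraries is unknown, and a peak missing from a list can lie below that list's calling limit. Different depths or thresholds change the number of peaks and hence the shared share.

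Peaks on chromosomes 1 to 19, X and Y were used, and peaks on other sequences were set aside and counted. No peaks overlapped others of their own list, so merging changed nothing. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The background was 1000 circular shifts, each of which moved all peaks of a chromosome by one random distance and kept their spacing. Chromosome ends were taken as the outermost bases of the peaks and genes, since chromosome lengths were not used here.

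Gene positions came from a RefSeq gene table on GRCm38.p6, which has the coordinates of mm10. The table gives the start and end of a gene and no strand, transcripts or exons. The planned location classes were therefore changed. A peak was placed by its midpoint within 1 kb of either annotated end of a gene, elsewhere inside a gene, or between genes, and promoters were not separated from the other end. Exons and introns were not separated. The planned search for the CTCF motif was not run, because no genome sequence was used here. All coordinates are 1-based mm10 positions.

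Gene lists were fixed before the data were examined: 14 lists, covering MGE, lateral and caudal eminence, dorsal and progenitor genes, migration, cohesin partners, imprinted genes, clustered protocadherins, Hox genes, ribosomal protein genes, olfactory receptors, cell cycle genes, and markers of blood and of vascular and meningeal cells. Each list was scored by the members with a peak overlapping 1 kb either side of a gene end, and by those with a peak in the gene or within 10 kb of it. Every member but 1 (Nespas) was matched. A list's share was set against 10000 random lists of protein-coding genes matched on 10 classes of gene length, and a list counted as above or below when its percentile reached 97.5 or 2.5. These percentiles describe the libraries and are not tests between tissues. Random lists hold genes from all over the genome. They vary too little to stand for lists whose members lie side by side, so each list was also set against 1000 circular shifts of the peaks, an alternative chosen after seeing the data. Shifted peaks lie anywhere on a chromosome, so lists of genes in gene-rich regions can exceed them without differing from other genes. The 56 combinations of list, window and library would give 2.8 positions outside the middle 95% by chance, and 13 were found. That expectation is too low for lists of genes that lie side by side. Olfactory receptor, Hox and protocadherin lists gave several of the 13. Positions also repeat, since olfactory receptor and ribosomal protein genes lay outside in both windows and both libraries.

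Genes are named by a rule fixed beforehand. It took from each list up to 3 genes with a gene-end peak in both lists, up to 2 with one in the MGE list alone and up to 2 with one in the telencephalon list alone. It also took a few genes fixed by name, among them Lhx6, Nkx2-1, Pax6 and Ctcf, the genes nearest to the 5 strongest peaks of each list and to the 5 strongest with no peak of the other list within 1 kb, and the 5 genes with the most peaks. The rule ranked peaks by score. Width took its place because the lists have no score. Some genes that the rule takes are not reported here. Any gene named outside the rule is marked as chosen after its values were seen. Other settings, fixed before the data were examined, varied the overlap, the windows, the genes used and the matching. Those that needed a score used peak width in its place, a choice made after seeing the data.

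Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. On simulated lists of 25625 peaks, planted shared shares of 20% and 60% were recovered as 20.6% and 60.3%. In simulated lists of 40 genes, 4.5% of random lists and 98% of lists with 4 times the odds of a peak fell outside the middle 95%.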

Results

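CTCF binding was mapped by ChIP-seq in the mouse telencephalon and in the MGE at embryonic day 13.5, with 1 CTCF library and 1 input library per tissue. The design asks where CTCF is bound in the developing forebrain and in its interneuron-producing ventral part. The MGE list held 25710 peaks, of which 25625 lay on chromosomes 1 to 19, X and Y. The telencephalon list held 31979 peaks, of which 31886 lay on these chromosomes. Peaks had a median width of 300 bp (interquartile range 244 to 376 bp) in the MGE list and 276 bp (205 to 376 bp) in the telencephalon list. They covered 8.37 Mb and 9.89 Mb of the genome. The narrowest width, 244 bp, was shared by 7399 MGE peaks (28.9%), whereas 1829 telencephalon peaks (5.74%) had that list's narrowest width, 150 bp. Neither tissue had a replicate, read depth is unknown, and all intervals are exact 95% Clopper-Pearson intervals of counting error.

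A large common set of CTCF peaks was found in both tissues. In the MGE list 14976 of 25625 peaks overlapped a telencephalon peak (58.4%, interval 57.8 to 59.0%), and 14984 of 31886 telencephalon peaks overlapped an MGE peak (47.0%, 46.4 to 47.5%). Circular shifts of the lists gave means of 0.807% and 0.654%, so the observed shares were 72.4-fold and 71.9-fold those of the shifts. The shared counts of the lists were nearly equal, and the shares differ with the lengths of the lists. The MGE list had 10649 peaks without a telencephalon partner and the telencephalon list had 16902 without an MGE partner. The widest MGE peaks all had partners. They lay inside Tacc2 (chr7:130761798-130762992, 1195 bp), inside Rimbp2 (chr5:128808611-128809776, 1166 bp), within 1 kb of an end of Pts (chr9:50528172-50529297, 1126 bp), inside another annotated gene 21641 bp from Tex35 (chr1:157076279-157077499, 1221 bp) and far from genes near Gm2244 (chr14:19416771-19418118, 1348 bp). Among the widest telencephalon peaks, those at Ercc1, a DNA repair nuclease gene (chr7:19342368-19344111, 1744 bp), at Sh2d6 (chr6:72534106-72535515, 1410 bp) and inside Ap5b1 (chr19:5568043-5569334, 1292 bp) were shared. Telencephalon peaks of 1642 and 1694 bp, side by side at chr12:59034996-59036637 and chr12:59036752-59038445 near Trappc6b, had no MGE partner.

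Sharing was higher among wider peaks in both lists. With the MGE list divided by width into 4 classes of equal size, 19.4% of peaks in the narrowest class were shared, and 52.1%, 73.8% and 88.4% in the following classes. The corresponding telencephalon shares were 11.4%, 34.3%, 62.5% and 79.8%. Peaks of equal width at a class border were divided by genome position, so MGE peaks of 244 bp fell in the narrowest class and the next. Shared peaks had a median width of 345 bp in the MGE list and 346 bp in the telencephalon list, against 244 bp and 223 bp for unshared peaks. The widest classes still held 742 MGE and 1611 telencephalon peaks with no partner. Among the widest MGE peaks without a telencephalon peak within 1 kb were those inside Arhgef12 (695 bp), Agps (679 bp) and Pou3f2 (657 bp), the last encoding a neural POU transcription factor, and far from genes with Pcdh20 (665 bp) as the nearest. Besides the pair near Trappc6b, the widest telencephalon peaks without an MGE peak lay inside Pla2g5 (1109 bp), near an end of Snapc5 and 100 bp from Rpl4 (1004 bp) and 31993 bp from Ccn5 (978 bp). Taking the widest 5000 peaks of each list, with partners counted only among the widest 5000 of the other, gave shared shares of 35.6% and 35.4%. That cut removes partners and does not mean that wide peaks were shared less.

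**Figure D1:**
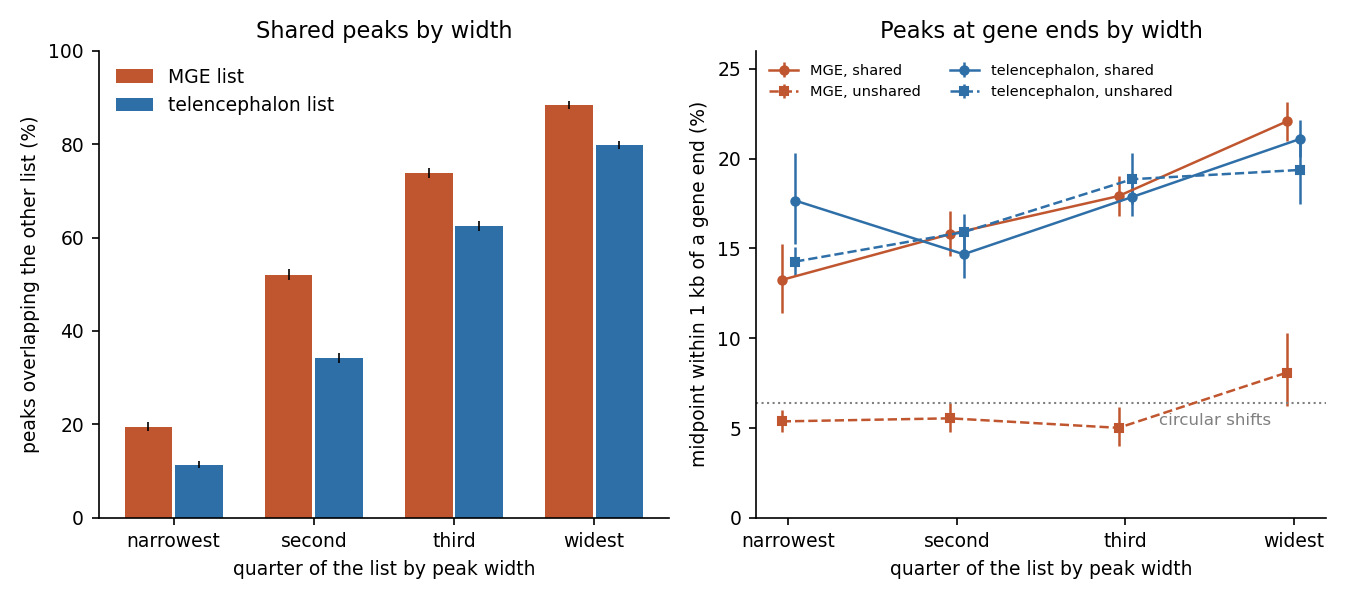
Left, share of peaks (%) that overlap the other list in 4 equal classes of peak width, rising from 19.4% to 88.4% in the MGE list and from 11.4% to 79.8% in the telencephalon list. Right, share of shared (solid) and unshared (dashed) peaks whose midpoint lies within 1 kb of a gene end, with the mean of circular shifts dotted; bars show exact 95% intervals of counting error, and unshared MGE peaks lie near the shifts.

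CTCF peaks were concentrated at gene ends, more so in the telencephalon list. Midpoints within 1 kb of a gene end made up 13.2% of MGE peaks (interval 12.8 to 13.6%) and 17.3% of telencephalon peaks (16.9 to 17.7%), or 2.08-fold and 2.69-fold the means of circular shifts. Shared peaks lay at gene ends in 18.6% of cases in each list. Unshared peaks of the lists parted: 5.55% of those in the MGE list (5.12 to 6.0%) and 16.1% of those in the telencephalon list (15.5 to 16.6%) lay at gene ends, which is 0.90-fold and 2.52-fold the shifted means. Unshared MGE peaks lay between genes in 52.0% of cases, against 35.4% for unshared telencephalon peaks. With gene ends taken as 500 bp, or with ends of protein-coding genes alone, unshared MGE peaks were at 1.01-fold of the shifts, so the small deficit turned over. Of 21883 protein-coding genes, 2302 had a gene-end peak in both lists, 345 in the MGE list but not the telencephalon list, and 1923 in the telencephalon list but not the MGE list.

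Genes of the MGE and cortical interneuron lineage carried CTCF peaks at gene ends in 6 of 35 cases in the MGE list and 8 of 35 in the telencephalon list. All 6 genes of the MGE list also had a gene-end peak in the telencephalon list. Gli1, a transcription factor of sonic hedgehog signalling, was among them (chr10:127342228-127342728 in MGE and chr10:127342296-127342827 in telencephalon). Cux2 had peaks at chr5:122050255-122050655 and chr5:122050307-122050708. Olig2, a ventral progenitor factor (chr16:91224824-91225070), and Etv1 (chr12:38780198-38780350) had a gene-end peak in the telencephalon list and not in the MGE list, where the nearest peaks lay 85499 bp and 62482 bp from the genes. The Olig2 peak was 247 bp wide, and the Etv1 peak, at 153 bp, fell in the narrowest class of the telencephalon list. Within 10 kb of the gene or inside it, 22 of 35 members had a peak in the MGE list (62.9%) and 26 of 35 in the telencephalon list (74.3%). Random lists of the same lengths averaged 53.9% and 64.1%, and both shares lay within their middle 95%. Against circular shifts of the peaks, which are not matched to genes, both shares lay above the range (means of 37.4% and 36.9%), and so did the gene-end shares (percentiles 99.4 and 100).

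At Nkx2-1, the transcription factor that specifies the MGE (chr12:56531935-56536908), a single shared peak lay 4164 bp from the gene in the MGE list (chr12:56541073-56541575) and 4204 bp from it in the telencephalon list (chr12:56541113-56541642). Lhx6, which acts downstream of Nkx2-1 in interneurons (chr2:36081950-36105992), had no peak within 20 kb in either list. The nearest was 73423 bp away in MGE and 36516 bp away in telencephalon. Pax6, a dorsal progenitor factor (chr2:105668896-105698410), likewise had none within 20 kb, with nearest peaks at 37843 bp and 52157 bp. Ctcf itself carried a shared peak at its lower-coordinate end, chr8:105636496-105637086 in MGE and chr8:105636570-105636895 in telencephalon. Peaks list the positions that passed calling, so a gene without one is not shown to be free of CTCF. Nor is a single peak shown to be bound by CTCF, since the motif was not sought and there is no replicate.

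Other forebrain lists also lay within the range of length-matched random lists at gene ends of 1 kb. With 5 kb ends the progenitor list lay above it in MGE (percentile 98.1). Against circular shifts these lists lay above the range in telencephalon at gene ends, as did the progenitor list in MGE (percentile 99.7), and all of them lay above it around the whole gene in both libraries. Genes of the lateral and caudal ganglionic eminences had a gene-end peak in 3 of 24 cases in MGE and 5 of 24 in telencephalon. Calb2, encoding calretinin, Ebf1 and Drd1, a dopamine receptor gene, had one in both lists, and Bcl11b and Meis1 in the telencephalon list but not the MGE list. Dorsal and excitatory genes had 3 of 30 and 5 of 30. Cux1, Lhx5 and Tbr1, a transcription factor of deep-layer cortical neurons, were in both, and Neurod6 and Wnt8b in the telencephalon list but not the MGE list. Progenitor genes had 5 of 26 and 7 of 26, with Slc1a3, Nes (nestin) and Hes1, an effector of Notch signalling, in both and Otx1 and Dll3 in the telencephalon list but not the MGE list. The peaks at Wnt8b, Otx1 and Dll3 (181, 189 and 165 bp) fell in the narrowest telencephalon class, where 88.6% of peaks were unshared. Those at Bcl11b, Meis1 and Neurod6 were 294, 260 and 222 bp wide. Counting the gene body and 10 kb around it, progenitor genes had a telencephalon peak in 22 of 26 cases (84.6%), above the middle 95% of random lists (46.2 to 80.8%). The MGE count, 17 of 26 (65.4%), lay within its range, and the difference was not tested. The telencephalon share fell back within the random range in the gene body alone (percentile 91.1), among the wider 50% of peaks (96.9) and with as many peaks as the MGE list (93.5).

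Migration and guidance genes had a gene-end peak in 4 of 40 cases in MGE and 9 of 40 in telencephalon. Sema3c, a secreted guidance cue, Plxna1, a semaphorin co-receptor, and Ackr3, a chemokine receptor, had one in both lists. Cdk5r1, an activator of the kinase Cdk5, had a 393 bp peak 30 bp from the gene in the MGE list (chr11:80476600-80476992), and the nearest telencephalon peak was 46539 bp away. Plxna2 and Cxcr4, a chemokine receptor that guides interneurons, had one in the telencephalon list but not the MGE list. The Cxcr4 peak (chr1:128592467-128592781) lay 167 bp from the gene, and the nearest MGE peak was 219128 bp away. Around the whole gene, 33 of 40 and 35 of 40 members had peaks, within the range of random lists and above that of circular shifts (percentiles 99.4 and 100).

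Genes for cohesin and CTCF partners had a gene-end peak in 8 of 25 cases in each list (32.0%, interval 15.0 to 53.5%). Random lists averaged 12.8% in MGE and 20.9% in telencephalon, so that the MGE share lay above the middle 95% and the telencephalon share within it. With ends taken as 5 kb the MGE share also lay within the range (percentile 95.7), and for the wider 50% of peaks the telencephalon share lay above it (percentile 99.5). Both shares lay above circular shifts. Bptf, a chromatin remodelling subunit, Esco1, a cohesin acetyltransferase, and Patz1, a zinc finger factor, had peaks in both lists. The gene-end peak of Zfp143 (chr7:110062628-110062879, 252 bp) was in the MGE list but not the telencephalon list. Stag2, a cohesin subunit gene on X, had one in telencephalon (chrX:42149060-42149362), and the nearest MGE peak lay 115865 bp away. Imprinted genes had gene-end peaks in 3 of 46 and 7 of 46 cases, within the random range. Against circular shifts they lay within the range at MGE gene ends and above it at telencephalon gene ends (percentile 98.8) and around the whole gene in MGE (98.05) and telencephalon (100). Kcnk9, H13 and Peg13 had them in both lists, and Magel2 (246 bp) and Peg10 (189 bp) in the telencephalon list but not the MGE list. H19 and Igf2, named after their values were seen because CTCF is known to insulate that locus, had no gene-end peak. Within 20 kb of H19 there were 1 MGE and 2 telencephalon peaks, with 1 MGE peak shared. That MGE peak (chr7:142581808-142582062) lay 3661 bp from H19 and overlapped a telencephalon peak of 1053 bp (chr7:142581126-142582178). Within 20 kb of Igf2 there were 2 in each list and none shared.

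**Figure D2:**
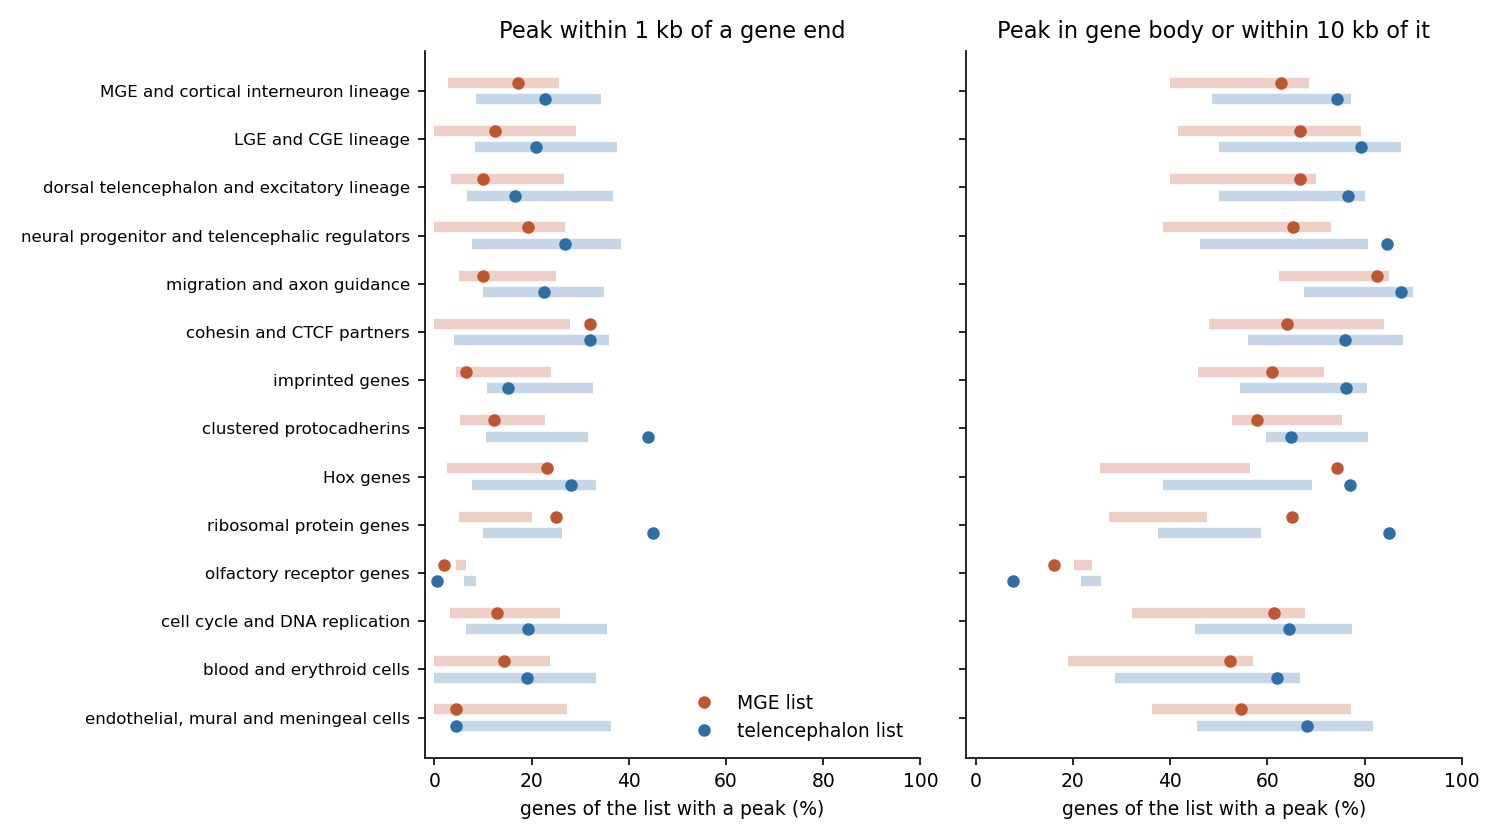
Share of the genes of each of the 14 lists (%) with a CTCF peak at a gene end (left) or in the gene and 10 kb around it (right); points are the observed shares per library and pale bars the middle 95% of 10000 random lists matched on gene length. Ribosomal protein genes lie above both bars, and olfactory receptor genes below.

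The Hox clusters, which pattern the body axis behind the forebrain, held a dense and nearly common set of peaks. Peaks lay in the gene or within 10 kb of it for 29 of 39 Hox genes in MGE (74.4%, interval 57.9 to 87.0%) and 30 of 39 in telencephalon (76.9%, 60.7 to 88.9%). Random lists averaged 41.6% and 53.4%. Circular shifts of the peaks, which keep neighbouring genes together, averaged 23.9% and 26.8%, with upper limits of 48.7% and 53.9%. Within the genes alone, without the 10 kb around them, the shares lay inside the random range (percentiles 73.1 and 77.6). In the genes and the 10 kb around them, 17 of 19 MGE peaks (89.5%) and 17 of 22 telencephalon peaks (77.3%) were shared. The Hoxa cluster (chr6:52155367-52260880) had 5 peaks in each list, all shared. The Hoxb cluster (chr11:96194316-96368254) had 7 MGE peaks and 11 telencephalon peaks, with 6 shared in each. The Hoxd cluster (chr2:74668225-74765142) had 4 and 5, with 4 shared, and the Hoxc cluster (chr15:102921131-103036856) had 3 and 3, with 2 shared. Hoxa10, Hoxb8 and Hoxd11 had a gene-end peak in both lists. Hoxb7 had one in telencephalon at chr11:96284583-96284795. The Hoxa9 difference was one of window size, since a shared peak lay 895 bp from the gene in telencephalon and 1015 bp from it in MGE.

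Clustered protocadherins, cell surface proteins chosen promoter by promoter in single neurons, had 12.5 MGE and 19.4 telencephalon peaks per Mb in the genes and 10 kb around them, against 9.47 and 10.4 on the whole of chromosome 18. In these windows 33 of 57 genes had a peak in MGE and 37 of 57 in telencephalon (57.9% and 64.9%). These shares lay within the range of random lists (means of 64.0% and 70.7%) and of circular shifts. The Pcdha cluster (chr18:36930285-37188897) had 3 peaks in each list, with 1 shared, and the Pcdhb cluster (chr18:37264998-37521419) had 2 MGE peaks and 1 telencephalon peak, none shared. The Pcdhg cluster (chr18:37661775-37841873) had 5 MGE and 10 telencephalon peaks, with 3 shared. Gene-end peaks were counted for 7 of 57 genes in MGE and 25 of 57 in telencephalon, but a single telencephalon peak (chr18:37841362-37841605, 244 bp) lay at the upper end that all 21 Pcdhg genes have in common. Counted at the lower ends, 7 of 57 (12.3%, interval 5.08 to 23.7%) and 11 of 57 (19.3%, 10.05 to 31.9%) had a peak. The intervals overlapped, and the difference was not tested. The 22 Pcdhb genes gave 0 of these in MGE and 1 in telencephalon. Pcdhac1, Pcdhga5 and Pcdhgb7 had a peak at the lower end in both lists. Pcdha11 had one in MGE (244 bp, the narrowest width of that list), and Pcdhga7 and Pcdhgc3 had one in telencephalon but not in MGE.

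**Figure D3:**
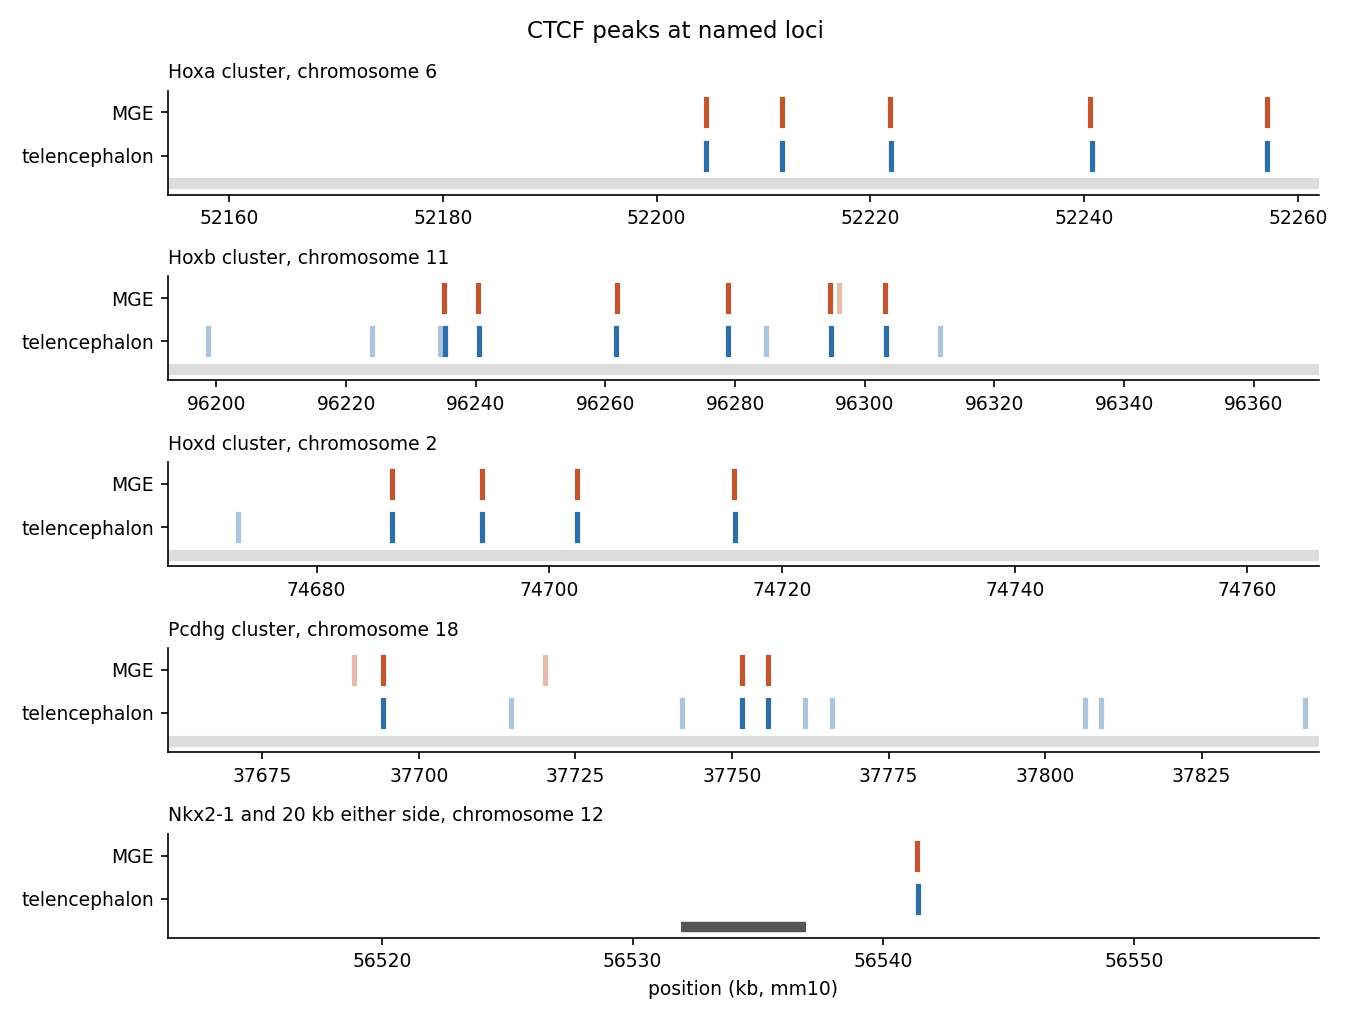
Positions (kb, mm10) of CTCF peaks of the MGE and telencephalon lists at 3 Hox clusters, the Pcdhg cluster and Nkx2-1. Lines mark peak midpoints at a fixed thickness, dark lines are shared peaks, pale lines unshared ones, and grey bars are the cluster or the gene; the 5 Hoxa peaks pair between the lists.

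Ribosomal protein genes, most of which are active in nearly every cell, were rich in CTCF peaks. At gene ends 20 of 80 had a peak in MGE (25.0%, interval 16.0 to 35.9%) and 36 of 80 in telencephalon (45.0%, 33.9 to 56.5%), against random means of 12.1% and 18.0%. Random lists drew on all protein-coding genes, among them 1106 olfactory receptor genes with few gene-end peaks, which can lower these means. Rpl38 (chr11:114668080-114668623 in MGE and chr11:114667817-114668625 in telencephalon) and Rpl26 had gene-end peaks in both lists. Rpl4 (chr9:64178663-64179666, 1004 bp) and Rpl27 (chr11:101441773-101442328, 556 bp) had wide gene-end peaks in telencephalon, with the nearest MGE peaks 34128 bp and 22020 bp away. Rpl32l had a 244 bp peak in MGE and none at its ends in telencephalon. In the gene or within 10 kb of it, 52 of 80 and 68 of 80 had peaks, above the random range in both lists. In these windows 64 of 69 MGE peaks were shared, but 64 of 115 telencephalon peaks.

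Olfactory receptor genes, which are silent outside sensory neurons and lie in large clusters, had few gene-end peaks: 21 of 1106 in MGE (1.90%, interval 1.18 to 2.89%) and 5 of 1106 in telencephalon (0.452%, 0.147 to 1.05%). Random lists averaged 5.50% and 7.30%. In the gene or within 10 kb of it, 179 of 1106 and 86 of 1106 had a peak, and both lay below the random range. Against circular shifts, which keep the clusters whole, the MGE share of 16.2% lay within the range, at percentile 2.8, and the telencephalon share of 7.78% below it, at percentile 0. Counting unshared MGE peaks alone, 144 of 1106 genes had one in these windows (13.02%), above the random range of 7.23 to 9.86%. This count was not set against circular shifts, and random lists vary too little for genes that lie side by side. The windows of olfactory receptor genes held 160 MGE peaks, 20.6% of them shared (14.6 to 27.7%), and 80 telencephalon peaks, 41.3% shared (30.4 to 52.8%).

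Cell cycle genes had gene-end peaks in 4 of 31 cases in MGE and 6 of 31 in telencephalon, including Mcm5, a helicase subunit gene, Trp53 and Rrm2 in both, and Bub1 and Mcm3 in the telencephalon list but not the MGE list. Markers of other cell types showed no excess over length-matched random genes. Blood and erythroid genes had 3 of 21 and 4 of 21, with Klf1 and Spi1 among those in both and C1qa in telencephalon but not in MGE. Endothelial, mural and meningeal genes had 1 of 22 in each list, at Col1a1. All these counts lay within the random range. Against circular shifts, blood genes lay above the range at telencephalon gene ends (percentile 98.7) and around the whole gene in MGE (99.0) and telencephalon (99.6), and vascular and meningeal genes around the whole gene in telencephalon (99.8). Cell cycle genes lay above it in both lists and windows.

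Chromosome X stood apart from the autosomes in both lists. It carried 714 MGE peaks, 217 of them shared (30.4%, interval 27.0 to 33.9%), and 712 telencephalon peaks, 216 shared (30.3%, 27.0 to 33.9%). On the 19 autosomes the shared share ran from 48.7% to 72.1% in the MGE list and from 44.3% to 50.8% in the telencephalon list. X had 4.18 MGE peaks and 4.17 telencephalon peaks per Mb, against at least 8.99 and 10.1 on any autosome. Shared peaks on X had median widths of 295 bp in MGE and 252.5 bp in telencephalon, below the autosomal ranges of 334 to 361 bp and 331 to 370 bp. The labels give no sex for the embryos. Chromosome Y had 23 and 33 peaks.

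**Figure D4:**
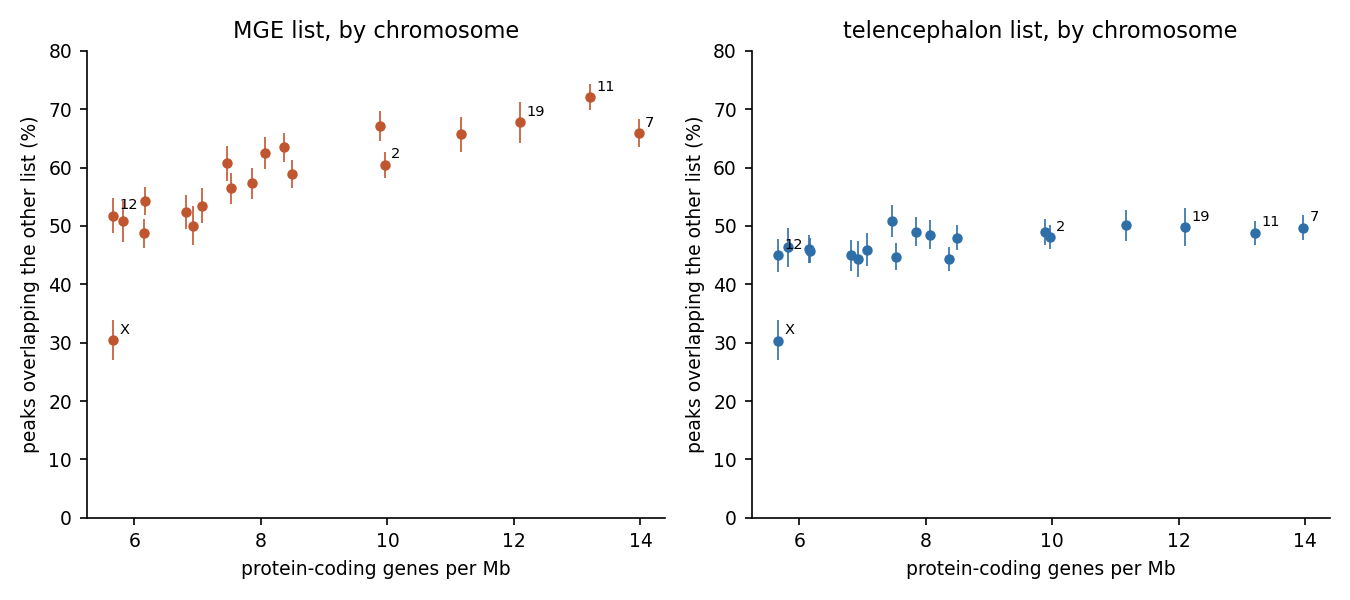
Share of peaks (%) overlapping the other list on each autosome and on X, against protein-coding genes per Mb, for the MGE list (left) and the telencephalon list (right). Bars are exact 95% intervals of counting error and some chromosomes are labelled; X, at 30.4% and 30.3%, lies below every autosome.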

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

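The tests of X copy number, of X gene density, of placement without regard to genes and of ribosomal protein genes were chosen only after the results were seen. The other tests were written down before.

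Clustered protocadherins had a gene-end peak in 43.9% of genes in the telencephalon list, above the random mean of 20.5%, and in 12.3% in the MGE list, below the random mean of 13.1%. The lists thus lay on opposite sides of their random means, and this difference was not tested. It rests on a single telencephalon peak at the upper end common to the 21 Pcdhg genes: at lower ends the counts were 11 of 57 and 7 of 57. With 5 kb ends the telencephalon share came to lie inside the random range (percentile 84.1), and for the wider 50% of peaks it was -6.88 percentage points from the random mean. Against circular shifts, which keep the genes together, the 1 kb telencephalon share lay above the range (upper limit 36.8%, percentile 99.8).

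Peaks also lay on sequences outside the chromosomes used, and those with more than the 3 peaks that a count of 0 allows are given. One unplaced sequence held 61 telencephalon and 47 MGE peaks within 107.4 kb, and 45 of the MGE peaks were shared. On an unlocalised sequence of chromosome 1 the telencephalon list had 6 peaks. On each of 2 unlocalised sequences of chromosome 4 the telencephalon list had 4 peaks, and the MGE list had 4 on another of chromosome 1, 4 on one of chromosome 5 and 4 on a further unplaced sequence.

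Of the MGE peaks, 41.6% had no telencephalon partner, and the labels do not say whether the telencephalon sample contained the MGE. Partners lying close by without overlap are argued against, since allowing gaps of up to 500 bp added 0.702 percentage points. Unshared MGE peaks showed no excess around MGE lineage genes, at percentile 70.9 of random lists, beside 67.1 for dorsal genes. The share of MGE lineage genes was 22.9%, within a wide random range of 8.57 to 31.4%. A modest excess would lie inside that range, so binding concentrated at MGE lineage genes stays open. It also stays open that many unshared MGE peaks may be calls near the calling limit. Of peaks at the minimum width 19.1% were shared, against 88.4% of the widest class. Unshared MGE peaks may also lie without regard to genes, at 0.898-fold of the shifts at gene ends. Around the whole gene, however, olfactory receptor genes had them more often than random lists (13.02% against 8.53%). So did clustered protocadherins (43.9% against 31.8%, percentile 98.65) and migration and guidance genes (24 of 40, percentile 99.6). With 100 length classes the migration list lay at percentile 93.7. Random lists vary too little for olfactory receptor and protocadherin genes, which lie side by side. Binding in the MGE away from the listed genes, a telencephalon sample without or with few MGE cells, and a difference in stage or calling threshold remain untested.

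Of the telencephalon peaks, 53.0% had no MGE partner, and these lay at gene ends 2.90 times as often as unshared MGE peaks did. Narrow peaks near the calling limit may account for part of the number, since 11.4% of the narrowest class were shared against 79.8% of the widest. Narrow width does not account for the position, because 19.4% of the unshared peaks in the widest class lay at gene ends. The lists hold no score, so the distance of a peak from either list's calling limit is unknown. Calls near a limit are therefore not excluded as a cause of the position. A candidate explanation is signal at gene ends particular to this library. The ratio of 2.90 restates the pattern, so it cannot decide that explanation. Ribosomal protein genes, active in most cells, had an unshared telencephalon peak at an end in 25.0% of cases against a random mean of 8.65%. Their share with an unshared MGE peak at an end lay within the random range. With all peaks counted, however, their gene-end share was above random lists in MGE too (25.0% against 12.1%). An excess at these genes was thus found in both lists, and it does not decide the explanation either. Tissue, library kit and any difference in stage or calling threshold cannot be told apart here, and without a genome sequence the CTCF motif was not sought in these peaks, so a biological difference stays open and untested.

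On X, 30.4% of MGE and 30.3% of telencephalon peaks were shared, fewer than on any autosome. Low gene density as the cause is argued against, since chromosome 12, with the nearest number of genes per Mb, had 45.0% of telencephalon peaks shared (interval 42.2 to 47.8%). Fewer copies of X than of each autosome may lower the signal on X, and the median width of shared telencephalon peaks was 252.5 bp there against at least 331 bp on each autosome. The sex of the embryos, the repeat content of X and read mappability were not examined.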

How the results depend on the processing

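The width-based settings, the 50 kb background, the lower-end count of protocadherins, the random lists without olfactory receptors and the circular shifts of peaks over gene lists were chosen after seeing the data. No paired analysis was possible because each tissue has 1 library. Settings fixed beforehand that ranked peaks by score were run with peak width in its place, since the lists have no score. The 5 for the CTCF motif were not run, as no genome was used. Peak lists hold no depth, so a missing peak sets no limit on binding. For the values below the cause was not tested, except that fewer peaks, or narrower and wider windows, change counts by construction.

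Shared shares (MGE, then telencephalon; 58.4% and 47.0% as reported) were 52.0% and 41.8% with 50% overlap of both peaks, 59.1% and 48.9% with gaps up to 500 bp, and 57.1% and 45.9% with midpoints within 200 bp. They were 66.7% and 53.6% for the wider 50% of each list, 81.1% and 71.2% for the wider 50% against the whole other list, 74.0% and 44.9% without peaks of minimum width, 56.1% and 56.1% with equal numbers of peaks, and 35.6% and 35.4% with the widest 5000. Equal numbers give nearly equal shares by construction.

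Gene-end enrichment over shifts kept its direction for all MGE, all telencephalon and unshared telencephalon peaks under each setting run: 2.52-fold, 3.32-fold and 3.12-fold with 500 bp ends, 1.52-fold, 1.83-fold and 1.73-fold with 5 kb, 2.86-fold, 3.73-fold and 3.53-fold with protein-coding genes, 2.74-fold, 3.004-fold and 2.99-fold for the wider 50%, and 1.58-fold, 1.80-fold and 1.78-fold against peaks moved 50 kb. Without minimum-width peaks the MGE value was 2.47-fold. Unshared MGE peaks, at 0.90-fold, turned to 1.01-fold both with 500 bp ends and with protein-coding genes, and were at 0.984-fold for the wider 50%.

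Protein-coding genes with a gene-end peak in both lists, in MGE alone and in telencephalon alone numbered 5612, 862 and 3337 with 5 kb ends. The wider 50% gave 1518 in both and 1100 in telencephalon alone. Without minimum-width peaks 194 were in MGE alone at gene ends, and 643 counting the body and 10 kb. The body alone gave 5899 in both. At 500 bp ends 3 lists lay below the random range in telencephalon. For the wider 50%, 2 lists lay below it at gene ends in MGE, and 4 above and 2 below for the body. With the body alone 1 list lay above in MGE and 1 in telencephalon, and with unmatched random lists 5 lay above for the telencephalon body. The protocadherin excess at telencephalon gene ends turned to -6.88 percentage points for the wider 50%. In the settings fixed beforehand, 126 positions of single lists were unchanged, 9 moved outside the random range and 5 moved into it. In those added, the numbers were 236, 38 and 3, apart from the 1 protocadherin position that turned and also came to lie inside the range, and circular shifts, which do not match on genes, gave 31 of the 38.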

Other observations

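The genes with the most CTCF peaks ranged in length from 379 to 2241 kb, and the counts are not adjusted for length. Lsamp, a cell adhesion gene of 2197 kb on chromosome 16, had 28 MGE and 20 telencephalon peaks in the gene and 10 kb around it. Dlg2, a synaptic scaffold gene, had 25 MGE and 9 telencephalon peaks, Macrod2 had 18 and 8, and Cntnap2, a neurexin family gene, had 16 and 8. Camta1 had 16 MGE and 24 telencephalon peaks, Asic2, an acid-sensing channel gene, 10 and 21, Fry 12 and 20, and Pde4d, a phosphodiesterase gene, 16 and 20. These differences have no replicate check.

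The migration and guidance list had 136 peaks in each library in the genes and 10 kb around them, and 24 of its 40 genes had an unshared MGE peak there. This lay at percentile 99.6 of random lists matched on 10 length classes and at 93.7 with 100 classes, as the list holds very long genes.

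On chromosome Y, 21 of 23 MGE peaks and 24 of 33 telencephalon peaks lay between 90718821 and 90840405. At Sox6, an interneuron transcription factor named after its values were seen, gene-end peaks of 309 bp (chr7:116040245-116040553) and 345 bp (chr7:116040239-116040583) overlapped.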
